A study of Homo sapiens with 5 samples.

How the data were processed

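Polyadenylated RNA of 5 libraries of H1 cells was sequenced at day 30 (GiWi, 2 libraries; YAP inhibitor with Activin, 3 libraries), on a HiSeq instrument from a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, STAR 2.5.1, HOMER, edgeR 3.16.1 and the hg19 build, with no role or order. The first table holds exon counts per gene, deposited by the authors and treated here like an expected count, because every value is a multiple of 0.5 and 34.6% are not whole, and they were rounded to whole numbers before testing. The second table holds FPKM values deposited by the authors. The summed gene counts come to 80.0 to 85.0% of the library totals that these values imply. Each table lists 27139 genes and 3 emptied rows, which were not used here. Coordinates are hg19 spans of the transcript each file gives for the gene.

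Groups were taken from the labels, and the comparison was the YAP inhibitor with Activin against GiWi. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05, which tested 17634 genes with a common dispersion of 0.0232. TMM factors were 1.1 and 1.07 for GiWi and 0.964, 0.954 and 0.926 for the others, in which the 10 most abundant genes took 18.1, 18.3 and 20.2% of counts, against 11.5 and 11.6% in GiWi. The design, the rule for named genes, 33 gene lists and all alternatives but 3 were fixed before the data were examined. Lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry, each with Benjamini-Hochberg adjustment over the lists. The estimated form rests on the 3 residual degrees of freedom of the fit, so a missing call there does not show that a list did not shift. With a group at 0 counts, a fold was computed from the other group's summed counts over its summed library sizes, against a floor of 3 counts over the group; with 1 to 3 counts, the ratio has an exact 95% interval. Intervals and floors cover counting error only. Replicates differed by more than sampling noise. The chi-square per degree of freedom was 5.91 for the GiWi pair and, in the other group, 2.13 for replicates 1 and 2, 53.7 for 1 and 3 and 48.5 for 2 and 3, over genes with at least 20 counts in the pair. Figures were drawn with matplotlib 3.10.9.

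The named genes were the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose mean reaches 10 CPM in the higher group, up to 4 members of each list with the smallest p, and 12 genes fixed by name. Symbols such as LOC and LINC are counted but not named. Some genes that the rule selects are not reported here, and they remain in the counts. Extending that exclusion to open reading frame and KIAA symbols was decided after the largest changes had been seen; it leaves out C2orf88, in whose place CNTNAP4 stands among the falls. Overlapping genes and near-identical paralogs, such as MYH6 and MYH7, FCGR3A and FCGR3B, and the histone genes, may share reads, and the strand setting of the counting is not given in the sources used here. Alternatives were RLE factors, library size alone, no filter and a stricter filter of at least 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom with sample weights, robust edgeR, limma on log2 FPKM with pseudocounts 1 and 0.1, each library left out in turn, and the replicate number as a block. The edgeR and camera steps were tested on simulated data for this comparison over 17411 genes: 91% of 100 genes changed by a log2 of 1 and 100% of 100 changed by 2 were recovered, with 10 false calls, and 0 of the unchanged lists were called. The simulated genes were drawn independently at the common dispersion, with few changed genes and no library apart from its group. The simulation therefore does not tell how many false calls of genes or lists the real data hold.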

Results

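Messenger RNA was sequenced from the H1 line, an established line of human embryonic stem cells, at day 30 of differentiation towards heart muscle by 1 of 2 protocols. In the GiWi protocol (2 libraries), a GSK3 inhibitor, which activates Wnt signalling, was followed by an inhibitor of that pathway. In the other protocol (3 libraries), cells received an inhibitor of YAP, the transcriptional coactivator that the Hippo pathway restrains, together with Activin, a ligand of the TGF-beta family. The labels give treatment times of 48 h for GiWi and 24 h for the YAP inhibitor with Activin, so protocol and treatment time differed together. The GiWi libraries held 48904302 and 48309765 exon counts. The libraries of the YAP inhibitor with Activin held 48825439, 44614520 and 43661188. The study set the protocols side by side to compare the transcriptomes of the resulting cardiomyocyte cultures. Values below are mean ± SD of TMM-scaled CPM (n = 2 for GiWi and n = 3 for the YAP inhibitor with Activin). A log2 fold change is the YAP inhibitor with Activin against GiWi, ± SE from edgeR, so a positive value means higher with the YAP inhibitor and Activin.

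The libraries separated by protocol. The first principal component held 90.5% of the variance and parted the protocols, and the second held 7.54% and parted replicate 3 of the YAP inhibitor with Activin from replicates 1 and 2. Across genes, which are not independent replicates, log2 CPM correlated at r = 0.997 within the GiWi pair and at 0.997 between replicates 1 and 2 of the other group. Replicate 3 correlated with those at 0.976 and 0.977. In replicate 3, the 39 tested sarcomere genes lay at a median log2 difference of -1.22 from the mean of replicates 1 and 2, and the blood and macrophage genes at -1.23, while the median of all tested genes was -0.0020. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

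C1QB, CD163 and RAX were among the genes that rose most with the YAP inhibitor and Activin, and AGTR2 and SHOX2 among those that fell most. C1QB rose from 0 counts to 67.3 ± 31.6 CPM, at least 2403-fold higher. CD163 rose from 0 counts to 23.4 ± 11.2 CPM, at least 838-fold higher; they encode a complement chain and a haemoglobin scavenger receptor of macrophages. RAX rose from 1 count in the GiWi libraries to 19.2 ± 2.95 CPM, a ratio of 2034 with a 95% counting interval of 365 to 80370; this homeobox gene marks the eye field. AGTR2 fell from 50.7 ± 4.38 to 0.739 ± 0.505 CPM (log2 fold change -6.12 ± 0.38, edgeR adjusted p = 1.61e-04); it encodes the type 2 angiotensin receptor. SHOX2 fell from 29 ± 0.572 to 0.581 ± 0.357 CPM (log2 fold change -5.65 ± 0.35, edgeR adjusted p = 1.64e-04); it encodes a transcription factor of the sinus node. Of 17634 genes tested, 10065 (57.1%) changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 5325 higher and 4740 lower, and 4115 of them changed by at least 2-fold, 2679 higher and 1436 lower. In 13373 genes (75.8%) all libraries of 1 group lay above those of the other, where chance gives 20% for independent libraries and more if some are technical repeats.

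Among the 12 largest rises, LILRB2, TYROBP and GPR34 had no counts in either GiWi library and were at least 637-fold, 504-fold and 375-fold higher. HLA-DRA rose from 1 count in the GiWi libraries to 22.5 ± 12.8 CPM, a ratio of 2429 with a 95% counting interval of 436 to 95983. ITGB2 rose from 2 counts in the GiWi libraries to 32 ± 13.4 CPM, a ratio of 1712 with a 95% counting interval of 474 to 14144. C1QC rose from 0.0377 ± 0.0259 to 59.8 ± 27.2 CPM (log2 fold change 10.52 ± 0.93). FCGR3A rose from 2 counts in the GiWi libraries to 31.5 ± 15.5 CPM, a ratio of 1691 with a 95% counting interval of 468 to 13967; its near-identical copy FCGR3B could share these reads. OTX2 rose from 1 count in the GiWi libraries to 18.5 ± 5.36 CPM, a ratio of 1968 with a 95% counting interval of 353 to 77778; it is a homeobox gene of forebrain and retina. CHP2 rose from 1 count in the GiWi libraries to 17.3 ± 8.23 CPM, a ratio of 1852 with a 95% counting interval of 332 to 73171. Among the 12 largest falls, PENK fell from 319 ± 0.51 to 6.93 ± 0.99 CPM (log2 fold change -5.52 ± 0.13); it encodes the precursor of enkephalin peptides. The others were SCNN1G (-6.03 ± 0.46), a subunit of the epithelial sodium channel, SBSPON (-5.69 ± 0.11), SLITRK2 (-5.65 ± 0.19), APELA (-5.11 ± 0.51), a ligand of the apelin receptor, SHISA3 (-5.00 ± 0.82), GRIA2 (-4.94 ± 0.14), a glutamate receptor subunit, DRD1 (-4.71 ± 0.15), the D1 dopamine receptor, JPH4 (-4.67 ± 0.45) and CNTNAP4 (-4.62 ± 0.32), each with its log2 fold change. In hg19, C1QB spans chromosome 1, 22979474 to 22988129, RAX chromosome 18, 56934267 to 56940625, AGTR2 chromosome X, 115301958 to 115306225 and SHOX2 chromosome 3, 157813800 to 157823952.

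The number of changed genes depended on the libraries, and their split into higher and lower depended on the scaling. Without GiWi replicate 1 it was 6070 (3326 higher, 2744 lower) and without GiWi replicate 2 it was 5909 (3301 higher, 2608 lower), with the lone GiWi library assumed to vary like the others. Of the calls, 52.9% were higher, against 35.8% with scaling by library size alone and 38.0% and 39.7% on log2(FPKM + 1) and log2(FPKM + 0.1). Scaling by library size alone put the median log2 fold change of all tested genes at -0.18, against 0.01, and log2(FPKM + 0.1) put it at -0.12.

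Transcripts of the contractile apparatus were present in both groups, and a few of its genes differed strongly. MYH6, the alpha myosin heavy chain, fell from 1867 ± 16.3 to 101 ± 45.4 CPM (log2 fold change -4.20 ± 0.43, edgeR adjusted p = 7.74e-04). MYL2, the ventricular regulatory light chain, rose from 4.56 ± 0.167 to 135 ± 58.3 CPM (log2 fold change 4.89 ± 0.51, edgeR adjusted p = 8.20e-04). MYOM3, a protein of the sarcomere M band, rose from 0.134 ± 0.0839 to 9.05 ± 2.13 CPM (log2 fold change 6.06 ± 0.43). DES, the muscle intermediate filament desmin, fell from 265 ± 8.5 to 101 ± 18.5 CPM (log2 fold change -1.40 ± 0.15). Other sarcomere genes did not pass the test: TNNT2 at 898 ± 10.1 and 635 ± 277 CPM, MYL7 at 863 ± 17.7 and 601 ± 244 CPM, TNNI1 at 573 ± 6.37 and 367 ± 149.8 CPM, and TNNI3 at 68.2 ± 2.73 and 41.3 ± 22.4 CPM, for cardiac troponin T, the atrial light chain, and slow skeletal and cardiac troponin I. The order of values is GiWi, then the YAP inhibitor with Activin. MYL7 and TNNI1 are also on the atrial list. Of the 39 sarcomere genes, 7 rose, 6 fell and 26 did not pass (2 and 5 adjusted over the list alone), and camera found no shift (adjusted p = 0.277). The median log2 fold change was -0.26.

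The sarcomere result depended on replicate 3 of the YAP inhibitor with Activin, in which all 39 sarcomere genes lay below the mean of replicates 1 and 2. TNNT2 measured 799, 789.7 and 315 CPM in replicates 1, 2 and 3. Without replicate 3, 15 sarcomere genes rose and 15 fell, and TNNT2, MYL7, TNNI1, TNNI3 and NKX2-5 fell by 0.18, 0.22, 0.34, 0.33 and 0.17 on the log2 scale, each past the threshold in edgeR. TNNI1 also passed with limma-voom and sample weights (adjusted p = 0.0323). With the replicate number as a block, replicate 3 has no GiWi library beside it and so drops out of the contrast. TNNT2, MYL7, TNNI1, TNNI3 and NKX2-5 passed there as well, and 15 sarcomere genes rose and 17 fell. Leaving out GiWi replicate 1 or 2 left 7 and 7 sarcomere genes past the test (2 higher and 5 lower in both cases), and leaving out replicate 1 or 2 of the other group left 8 and 8 (2 higher and 6 lower in both cases). With scaling by library size alone, 3 rose and 7 fell.

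**Figure D1:**
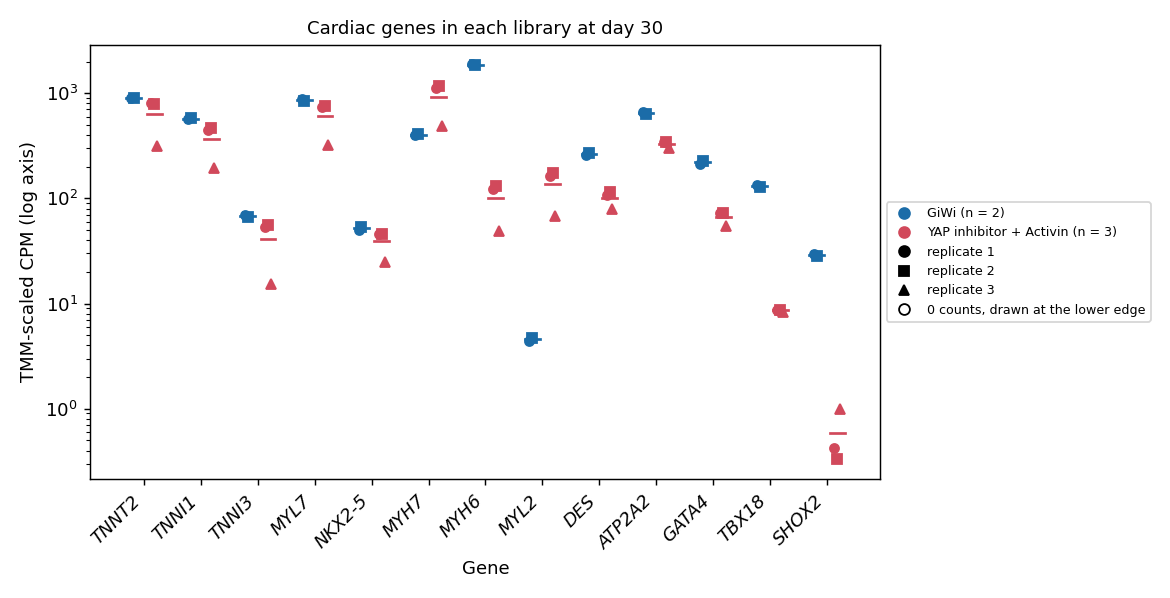
TMM-scaled CPM on a log axis for 13 cardiac genes, with 1 point per library, horizontal bars for group means and symbols for the replicate number (GiWi, n = 2; YAP inhibitor with Activin, n = 3). MYH6 lay at 1867 CPM in GiWi and 101 with the YAP inhibitor and Activin, MYL2 at 4.56 and 135, and replicate 3 was the lowest library for TNNT2, at 315 CPM.

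Genes of calcium handling and ion conduction were more often lower than higher with the YAP inhibitor and Activin. ATP2A2, the calcium pump of the sarcoplasmic reticulum, fell from 643 ± 18.8 to 329 ± 25.7 CPM (log2 fold change -0.97 ± 0.08, edgeR adjusted p = 3.84e-04). PPP1R1A, a protein phosphatase 1 inhibitor, fell from 83.2 ± 5.75 to 9.58 ± 4.7 CPM (log2 fold change -3.11 ± 0.43). KCNA5, an atrial potassium channel, fell from 25.9 ± 0.615 to 1.9 ± 0.128 CPM (log2 fold change -3.77 ± 0.09). ITPR2, an inositol trisphosphate receptor, rose from 12.7 ± 0.784 to 56.4 ± 2.19 CPM (log2 fold change 2.15 ± 0.07). KCNE4, a potassium channel subunit, rose from 39.2 ± 1.46 to 82.4 ± 3.39 CPM (log2 fold change 1.07 ± 0.06). Of the 26 calcium handling genes, 2 rose, 10 fell and 14 did not pass (2 and 7 adjusted over the list alone), without a shift in camera (adjusted p = 0.151). Of the 32 ion channel and gap junction genes, 7 rose, 14 fell and 11 did not pass (7 and 14 adjusted over the list alone). Camera on ion channel and gap junction genes gave an adjusted p = 0.0243, and an adjusted p = 0.562 with an estimated correlation. Of the calcium handling genes, 6 and 5 passed without GiWi replicate 1 or 2, and 23 without replicate 3 of the YAP inhibitor with Activin, in which this list lay at a median of -0.56 log2 from replicates 1 and 2. The camera call of the ion channel list was lost with scaling by library size alone (adjusted p = 0.119).

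Atrial and pacemaker genes were more often lower than higher with the YAP inhibitor and Activin, and several ventricular genes rose. MYL2 amounted to 0.529 ± 0.0301% of MYL7 in GiWi and 22.3 ± 0.889% with the YAP inhibitor and Activin. MYH6 made up 82.2 ± 0.473% of the CPM of MYH6 and MYH7 together in GiWi and 9.73 ± 0.522% in the other group. All 3 libraries of the YAP inhibitor with Activin, replicate 3 included, lay apart from both GiWi libraries in each ratio; the exact two-sided permutation test gave p = 0.1, the smallest that 10 splits allow. MYH7, the beta myosin heavy chain, rose from 404 ± 9.54 to 925 ± 379 CPM (log2 fold change 1.19 ± 0.38, edgeR adjusted p = 0.0405). The MYH7 call was lost without GiWi replicate 1 or 2 (edgeR adjusted p = 0.18 and 0.171), without replicate 1 or 2 of the other group (0.0946 and 0.0965) and with those replicates summed (0.0972). It was also lost with scaling by library size alone (0.0696) and by limma on log2(FPKM + 1) and log2(FPKM + 0.1) (adjusted p = 0.0930 and 0.0821), and its adjusted p ran from 9.27e-17 to 0.18 over all alternatives but the replicate block. TNNI3 made up 10.6 ± 0.486% and 9.6 ± 1.91% of TNNI1 and TNNI3 together (exact permutation p = 0.8). In hg19, MYH6 spans chromosome 14, 23851199 to 23877486, its paralog MYH7 chromosome 14, 23881947 to 23904895, and MYL2 chromosome 12, 111348624 to 111358404.

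Of the 25 atrial genes, 2 rose, 14 fell and 9 did not pass (2 and 14 adjusted over the list alone). Camera on atrial genes gave an adjusted p = 1.04e-04, and an adjusted p = 0.362 with an estimated correlation. VSNL1 fell from 36.9 ± 2.35 to 7.79 ± 0.585 CPM (log2 fold change -2.24 ± 0.09). BMP10, a growth factor of atrial muscle, fell from 6.7 ± 0.0757 to 0.558 ± 0.0611 CPM (log2 fold change -3.58 ± 0.16). An atrial list member of another kind was COMP, a cartilage matrix protein, which rose from 0.768 ± 0.0481 to 348 ± 91.8 CPM (log2 fold change 8.82 ± 0.34). Of the 22 pacemaker and conduction genes, 2 rose, 14 fell and 6 did not pass (2 and 15 adjusted over the list alone). Camera on pacemaker and conduction genes gave an adjusted p = 4.34e-06, and an adjusted p = 0.194 with an estimated correlation. TBX18, a transcription factor of the sinus node and epicardium, fell from 130.2 ± 4.2 to 8.6 ± 0.215 CPM (log2 fold change -3.92 ± 0.06, edgeR adjusted p = 1.23e-05). BMP2 fell from 45.2 ± 0.0499 to 10.6 ± 1.28 CPM (log2 fold change -2.09 ± 0.10). Of the 20 ventricular genes, 9 rose, 2 fell and 9 did not pass (10 and 2 adjusted over the list alone), and camera did not pass (adjusted p = 0.0581). MASP1 rose from 14.1 ± 0.267 to 59.1 ± 6.11 CPM (log2 fold change 2.06 ± 0.11). GJA1, the gap junction protein connexin 43, rose from 237 ± 7.8 to 430.5 ± 39.2 CPM (log2 fold change 0.86 ± 0.09). Without replicate 3 of the YAP inhibitor with Activin, 14 ventricular genes rose and 3 fell and camera passed (adjusted p = 1.19e-04, and an adjusted p = 0.252 with an estimated correlation). Camera also passed with scaling by library size alone (adjusted p = 0.0289, and an adjusted p = 0.771 with an estimated correlation); without GiWi replicate 1 or 2, 5 and 5 passed. In replicate 3 the ventricular list lay at a median of -0.64 log2 from replicates 1 and 2, the atrial list at -0.35 and the pacemaker list at -0.0091. Over replicates 1, 2 and 3, MYL2 (164, 174 and 68.4 CPM) and MYH7 (1110.5, 1175.2 and 489 CPM) were lowest in replicate 3, as TNNT2 was. GJA1 (406, 410 and 476 CPM) rose there, and KCNE4 (81.2, 86.3 and 79.8 CPM) and MASP1 (62.5, 62.6 and 52 CPM) fell less. Which cells these transcripts came from was not tested. Atrial genes that fell numbered 9 without GiWi replicate 2, and those that rose numbered 4 without replicate 3 of the other group.

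Cardiac transcription factors were more often lower than higher with the YAP inhibitor and Activin. GATA4 fell from 221 ± 11.3 to 66.6 ± 10.5 CPM (log2 fold change -1.73 ± 0.14, edgeR adjusted p = 3.54e-04). TBX5 fell from 83.7 ± 1.02 to 6.01 ± 2.23 CPM (log2 fold change -3.79 ± 0.30); both encode regulators of cardiac gene expression. ZFPM2, a cofactor of GATA4, fell from 83.6 ± 1.78 to 31.1 ± 2.64 CPM (log2 fold change -1.43 ± 0.08). TBX2 fell from 55.8 ± 2.27 to 27.5 ± 1.05 CPM (log2 fold change -1.02 ± 0.06). NKX2-5 measured 51.8 ± 1.87 CPM in GiWi and 38.9 ± 12.3 CPM in the other group and did not pass, and NR2F2, an atrial regulator, fell from 73.4 ± 0.125 to 48.8 ± 7.6 CPM (log2 fold change -0.59 ± 0.13, edgeR adjusted p = 0.0109); that call was lost without GiWi replicate 1 or 2 (edgeR adjusted p = 0.0674 and 0.0701, in a range from 4.70e-11 over all alternatives but the replicate block). Of the 39 cardiac transcription factors, 7 rose, 20 fell and 12 did not pass (7 and 21 adjusted over the list alone). Camera on cardiac transcription factors gave an adjusted p = 2.16e-04, and an adjusted p = 0.532 with an estimated correlation. Without GiWi replicate 1 or 2, 3 and 3 transcription factors rose and 16 and 16 fell. Of the 10 first heart field genes, 1 rose, 5 fell and 4 did not pass (1 and 5 adjusted over the list alone). Camera on first heart field genes gave an adjusted p = 0.0153, and an adjusted p = 0.718 with an estimated correlation; the call was lost with scaling by library size alone (adjusted p = 0.072). SFRP5, a secreted Wnt antagonist, fell from 278 ± 15.4 to 25.2 ± 6.38 CPM (log2 fold change -3.47 ± 0.22), while MYL2 was the member that rose. Of the 17 second heart field genes, 7 rose, 7 fell and 3 did not pass (8 and 7 adjusted over the list alone), without a shift in camera (adjusted p = 0.75). LHX2 rose from 1.92 ± 0.261 to 7.22 ± 0.451 CPM (log2 fold change 1.91 ± 0.15); it is also a gene of the eye field, as is RAX, which rose too. FGF10 rose from 2.45 ± 0.0199 to 7.0 ± 0.907 CPM (log2 fold change 1.51 ± 0.15). Without GiWi replicate 2, 9 second heart field genes passed, and without replicate 3 of the other group 2 first heart field genes rose. In that replicate the first heart field list lay at a median of -0.80 log2 from replicates 1 and 2.

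Most genes of the extracellular matrix rose with the YAP inhibitor and Activin. LUM, the collagen-binding proteoglycan lumican, rose from 280.5 ± 28.4 to 2210.4 ± 116 CPM (log2 fold change 2.98 ± 0.10, edgeR adjusted p = 2.80e-05). LOX, which cross-links collagen and elastin, rose from 284 ± 6.62 to 1445 ± 55.2 CPM (log2 fold change 2.35 ± 0.06). VCAN, the proteoglycan versican, rose from 632 ± 11.2 to 2558 ± 97.6 CPM (log2 fold change 2.02 ± 0.06). ELN, elastin, fell from 427 ± 9.19 to 177 ± 3.49 CPM (log2 fold change -1.27 ± 0.05). Of the 39 fibroblast and matrix genes, 26 rose, 7 fell and 6 did not pass (26 and 8 adjusted over the list alone). Camera on fibroblast and matrix genes gave an adjusted p = 6.70e-06, and an adjusted p = 0.562 with an estimated correlation. Epicardial and mesothelial genes were more often lower. ITLN1, the mesothelial lectin intelectin 1, fell from 627 ± 6.62 to 31.5 ± 4.46 CPM (log2 fold change -4.31 ± 0.13). PRG4, the lubricating proteoglycan 4, fell from 195 ± 13.1 to 9.94 ± 2.52 CPM (log2 fold change -4.29 ± 0.20), while ALDH1A1 rose from 8.1 ± 0.90 to 66.5 ± 7.61 CPM (log2 fold change 3.04 ± 0.14). Of the 27 epicardial and mesothelial genes, 8 rose, 15 fell and 4 did not pass (8 and 15 adjusted over the list alone). Camera on epicardial and mesothelial genes gave an adjusted p = 0.00447, and an adjusted p = 0.718 with an estimated correlation. Without GiWi replicate 1 or 2, 4 and 5 epicardial genes rose, and without GiWi replicate 2, 4 matrix genes fell. In replicate 3 the epicardial list lay at a median of 0.72 log2 from replicates 1 and 2.

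Endothelial and smooth muscle genes changed in both directions. FLT1, a VEGF receptor, rose from 8.88 ± 0.371 to 218 ± 43.1 CPM (log2 fold change 4.62 ± 0.22, edgeR adjusted p = 7.18e-05). ERG rose from 11.3 ± 0.642 to 29.8 ± 0.285 CPM (log2 fold change 1.40 ± 0.06), while NPR3, a natriuretic peptide receptor of the endocardium, fell from 172 ± 3.85 to 33.6 ± 3.94 CPM (log2 fold change -2.36 ± 0.10). LYVE1 rose from 3 counts in the GiWi libraries to 4.87 ± 0.98 CPM, a ratio of 172 with a 95% counting interval of 58.7 to 838; it marks lymphatic endothelium and some macrophages. Of the 33 endothelial and endocardial genes, 10 rose, 13 fell and 10 did not pass (11 and 15 adjusted over the list alone), without a shift in camera (adjusted p = 0.278); the median log2 fold change was -0.24 and the mean 0.02. TAGLN rose from 523 ± 36.3 to 1025 ± 58 CPM (log2 fold change 0.97 ± 0.08). SYNPO2 rose from 52.6 ± 2.08 to 162 ± 16.7 CPM (log2 fold change 1.62 ± 0.10). CALD1 rose from 572 ± 13.1 to 783 ± 6.26 CPM (log2 fold change 0.45 ± 0.05), while MYH11, the smooth muscle myosin heavy chain, fell from 83.3 ± 1.11 to 16 ± 5.56 CPM (log2 fold change -2.38 ± 0.29). Of the 18 smooth muscle genes, 8 rose, 5 fell and 5 did not pass (8 and 5 adjusted over the list alone). Camera on smooth muscle genes gave an adjusted p = 0.576, and with scaling by library size alone 5 rose and 7 fell. Endothelial genes past the test numbered 14 and 14 without GiWi replicate 1 or 2, and smooth muscle genes 5 and 6.

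YAP1, the gene of the coactivator that the inhibitor targets, was lower at day 30, and targets of YAP went both ways. YAP1 fell from 223 ± 11.6 to 159.6 ± 6.75 CPM (log2 fold change -0.48 ± 0.06, edgeR adjusted p = 0.00186). F3, tissue factor, rose from 3.07 ± 0.0718 to 23.6 ± 1.01 CPM (log2 fold change 2.94 ± 0.08). DOCK5 rose from 1.71 ± 0.119 to 35 ± 4.79 CPM (log2 fold change 4.36 ± 0.16). NT5E, which makes extracellular adenosine, rose from 0.369 ± 0.139 to 11.1 ± 0.697 CPM (log2 fold change 4.90 ± 0.23). Of the 32 YAP and TEAD target genes, 14 rose, 11 fell and 7 did not pass (14 and 12 adjusted over the list alone), and with scaling by library size alone 12 rose and 16 fell. Without replicate 3 of the YAP inhibitor with Activin, 14 rose and 15 fell, and without GiWi replicate 2, 12 rose and 7 fell. The median log2 fold change of this list was -0.01, its mean 0.57 and the camera test, which pointed upwards, had an adjusted p = 0.374. Of the 25 genes of the Hippo pathway, 3 rose, 11 fell and 11 did not pass (3 and 11 adjusted over the list alone). Camera on genes of the Hippo pathway gave an adjusted p = 0.0573. FAT4 fell from 197 ± 4.36 to 109 ± 6.38 CPM (log2 fold change -0.85 ± 0.07). DCHS1 fell from 277 ± 5.42 to 93.4 ± 13.9 CPM (log2 fold change -1.57 ± 0.12); FAT4 and DCHS1 are cadherins that bind each other. MOB1B fell from 29.1 ± 3.17 to 15.5 ± 0.558 CPM (log2 fold change -0.91 ± 0.09), while FRMD6 rose from 31.7 ± 1.31 to 63.6 ± 1.28 CPM (log2 fold change 1.01 ± 0.06). The Hippo list passed camera without GiWi replicate 2 (adjusted p = 0.0394), without replicate 3 of the YAP inhibitor with Activin (0.0292) and with scaling by library size alone (0.0363), where 2 rose and 17 fell. With an estimated correlation those settings gave an adjusted p = 0.763, 0.291 and 0.771, in that order.

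Nearly all genes of cell division were lower with the YAP inhibitor and Activin. TOP2A, topoisomerase II alpha, fell from 162 ± 8.56 to 59.8 ± 2.39 CPM (log2 fold change -1.44 ± 0.06, edgeR adjusted p = 6.17e-05). CENPF, a kinetochore protein, fell from 79.8 ± 3.19 to 26.3 ± 0.659 CPM (log2 fold change -1.60 ± 0.06). BUB1B, a spindle checkpoint kinase, fell from 33.6 ± 0.0408 to 13.1 ± 0.402 CPM (log2 fold change -1.35 ± 0.06). CCNA2, cyclin A2, fell from 33.7 ± 0.99 to 14.6 ± 0.145 CPM (log2 fold change -1.21 ± 0.05). Of the 45 cell cycle genes, 0 rose, 42 fell and 3 did not pass (0 and 42 adjusted over the list alone). Camera on cell cycle genes gave an adjusted p = 1.92e-17, and an adjusted p = 0.194 with an estimated correlation. Replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that the kit selects, were more often higher. HIST1H1C rose from 3.54 ± 0.248 to 8.69 ± 0.892 CPM (log2 fold change 1.30 ± 0.13). HIST1H2AC rose from 3.69 ± 0.0512 to 11.7 ± 2.05 CPM (log2 fold change 1.67 ± 0.18). Of the 12 histone genes, 6 rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone). Camera on histone genes gave an adjusted p = 0.0692, and 4 and 5 passed without GiWi replicate 1 or 2. With scaling by library size alone it gave an adjusted p = 0.0363, and an adjusted p = 0.771 with an estimated correlation.

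Genes of energy metabolism changed in both directions, mostly by small amounts. SLC2A1, the glucose transporter GLUT1, rose from 88.4 ± 1.09 to 263 ± 11.2 CPM (log2 fold change 1.57 ± 0.06, edgeR adjusted p = 4.63e-05). SLC16A3, a lactate transporter, rose from 53.7 ± 0.403 to 118 ± 4.0 CPM (log2 fold change 1.14 ± 0.06). HK2, hexokinase 2, rose from 21.2 ± 0.0946 to 34 ± 1.88 CPM (log2 fold change 0.68 ± 0.07), while ALDOC, an aldolase, fell from 99.7 ± 2.67 to 35 ± 6.19 CPM (log2 fold change -1.51 ± 0.15). Of the 31 glycolysis genes, 7 rose, 10 fell and 14 did not pass (7 and 10 adjusted over the list alone). Camera on glycolysis genes gave an adjusted p = 0.374. LPL, lipoprotein lipase, rose from 2.69 ± 0.417 to 21.8 ± 7.62 CPM (log2 fold change 3.01 ± 0.37). ACADVL, which oxidises very long chain acyl-CoA, rose from 105 ± 3.92 to 149.6 ± 2.25 CPM (log2 fold change 0.51 ± 0.05), while PDK2 fell from 85.3 ± 7.4 to 49.3 ± 0.766 CPM (log2 fold change -0.79 ± 0.07). Of the 39 fatty acid oxidation genes, 14 rose, 3 fell and 22 did not pass (12 and 3 adjusted over the list alone). Camera on fatty acid oxidation genes gave an adjusted p = 0.277. COX7A2 rose from 45.1 ± 1.2 to 70.0 ± 2.09 CPM (log2 fold change 0.63 ± 0.06). UQCRQ rose from 47.3 ± 4.52 to 82.5 ± 3.5 CPM (log2 fold change 0.80 ± 0.08); both genes are of the respiratory chain. In contrast, SLC25A3, the mitochondrial phosphate carrier, fell from 326 ± 11.3 to 251 ± 5.2 CPM (log2 fold change -0.38 ± 0.05). Of the 58 oxidative phosphorylation genes, 19 rose, 14 fell and 25 did not pass (19 and 14 adjusted over the list alone). Camera on oxidative phosphorylation genes gave an adjusted p = 0.795. With scaling by library size alone the balance turned, with 5 higher and 7 lower for fatty acid oxidation and 6 and 22 for oxidative phosphorylation, and 4 glycolysis genes were higher and 14 lower. With GiWi replicate 1 or 2 left out, 10 and 10 glycolysis, 6 and 5 fatty acid oxidation and 16 and 11 oxidative phosphorylation genes passed, the last with 7 higher and 9 lower without replicate 1. Of the fatty acid oxidation genes, 8 passed without replicate 2 of the other group and 28 without its replicate 3. Without its replicate 1, 9 fatty acid oxidation genes rose, without its replicate 2, 4 glycolysis genes rose, and without its replicate 3, 31 oxidative phosphorylation genes rose.

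Stress, hypoxia and immediate early genes were more often higher with the YAP inhibitor and Activin. GDF15, a stress-induced cytokine, rose from 1.55 ± 0.0288 to 26 ± 2.23 CPM (log2 fold change 4.07 ± 0.12, edgeR adjusted p = 2.29e-05). ATF3 rose from 6.07 ± 0.279 to 15.3 ± 1.18 CPM (log2 fold change 1.34 ± 0.10). UCHL1 rose from 165 ± 8.53 to 253 ± 5.21 CPM (log2 fold change 0.62 ± 0.06). ACTA1 rose from 6.05 ± 0.271 to 11.9 ± 1.64 CPM (log2 fold change 0.97 ± 0.14). Of the 15 natriuretic peptide and stress genes, 11 rose, 1 fell and 3 did not pass (11 and 1 adjusted over the list alone). The gene that fell was NPPA, atrial natriuretic peptide, from 513 ± 15.6 to 138 ± 69.4 CPM (log2 fold change -1.89 ± 0.46); it was chosen after its values were seen, and no gene of this list fell without GiWi replicate 1 or 2. Camera on natriuretic peptide and stress genes gave an adjusted p = 0.0223, and an adjusted p = 0.718 with an estimated correlation. P4HA1 rose from 227 ± 9.73 to 593 ± 12 CPM (log2 fold change 1.38 ± 0.06). PLOD2 rose from 136 ± 5.05 to 362 ± 12.2 CPM (log2 fold change 1.42 ± 0.06); both encode collagen-modifying hydroxylases. Of the 29 hypoxia genes, 15 rose, 4 fell and 10 did not pass (15 and 4 adjusted over the list alone). Camera on hypoxia genes gave an adjusted p = 0.0223, and an adjusted p = 0.562 with an estimated correlation. EGR2 rose from 0.827 ± 0.0876 to 16.7 ± 1.29 CPM (log2 fold change 4.33 ± 0.13). EGR1 rose from 14.4 ± 1.03 to 28.7 ± 0.458 CPM (log2 fold change 0.99 ± 0.07). JUNB rose from 42.7 ± 2.9 to 104 ± 8.37 CPM (log2 fold change 1.28 ± 0.09), while NR4A3 fell from 8.34 ± 0.341 to 2.43 ± 0.252 CPM (log2 fold change -1.78 ± 0.13). Of the 33 immediate early and heat shock genes, 21 rose, 5 fell and 7 did not pass (21 and 5 adjusted over the list alone). Camera on immediate early and heat shock genes gave an adjusted p = 0.00447, and an adjusted p = 0.562 with an estimated correlation. Among the stress genes, 5 and 5 passed without GiWi replicate 1 or 2. With scaling by library size alone, 6 stress genes rose and 2 fell, and 17 immediate early and heat shock genes rose and 8 fell; without replicate 3 of the YAP inhibitor with Activin, 8 of the latter fell, and 13 stress genes rose and 2 fell. In that replicate the stress list lay at a median of -0.78 log2 from replicates 1 and 2.

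Most genes of the endoderm, neural and blood lists were higher with the YAP inhibitor and Activin. CDX2, an intestinal homeobox gene, rose from 0.17 ± 0.0764 to 46.1 ± 10.6 CPM (log2 fold change 8.05 ± 0.38, edgeR adjusted p = 7.46e-05). CLDN4, an epithelial claudin, rose from 0.881 ± 0.153 to 63.6 ± 2.37 CPM (log2 fold change 6.17 ± 0.12). FOXA1 rose from 0.503 ± 0.0278 to 24.9 ± 3.56 CPM (log2 fold change 5.62 ± 0.19). TTR, transthyretin, rose from 3.84 ± 0.095 to 225 ± 45.3 CPM (log2 fold change 5.87 ± 0.22). ELF3 rose from 3.04 ± 0.102 to 63.8 ± 10.3 CPM (log2 fold change 4.39 ± 0.17). Of the 43 endoderm, hepatic and gut genes, 32 rose, 3 fell and 8 did not pass (32 and 3 adjusted over the list alone). Camera on endoderm, hepatic and gut genes gave an adjusted p = 1.53e-08, and an adjusted p = 0.438 with an estimated correlation. PAX6, a homeobox gene of eye and brain, rose from 0.0483 ± 0.0683 to 14.5 ± 0.403 CPM (log2 fold change 8.17 ± 0.48, edgeR adjusted p = 1.40e-04). FABP7 rose from 1.72 ± 0.253 to 29.2 ± 1.58 CPM (log2 fold change 4.08 ± 0.12). INA, a neuronal intermediate filament, rose from 1.5 ± 0.0103 to 11.9 ± 1.23 CPM (log2 fold change 2.98 ± 0.14), while NCAM1 fell from 425 ± 1.59 to 93.7 ± 8.0 CPM (log2 fold change -2.18 ± 0.08). Of the 33 neural and neural crest genes, 25 rose, 5 fell and 3 did not pass (25 and 5 adjusted over the list alone). Camera on neural and neural crest genes gave an adjusted p = 7.50e-05, and an adjusted p = 0.562 with an estimated correlation. CD68, a lysosomal protein of macrophages, rose from 4.11 ± 0.196 to 133 ± 38.3 CPM (log2 fold change 5.01 ± 0.33, edgeR adjusted p = 1.94e-04). CSF1R, the receptor for macrophage growth factor, rose from 0.153 ± 0.0575 to 39.9 ± 17.1 CPM (log2 fold change 8.01 ± 0.72). LMO2 rose from 0.428 ± 0.0509 to 2.47 ± 0.119 CPM (log2 fold change 2.52 ± 0.20). CD14 rose from 0.0377 ± 0.0259 to 7.25 ± 1.98 CPM (log2 fold change 7.48 ± 0.50). Of the 16 blood and macrophage genes, 13 rose, 1 fell and 2 did not pass (13 and 1 adjusted over the list alone). Camera on blood and macrophage genes gave an adjusted p = 5.31e-05, and an adjusted p = 0.562 with an estimated correlation. In replicate 3 these lists lay at medians of -0.62, -0.38 and -1.23 log2 from replicates 1 and 2, in that order.

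**Figure D2:**
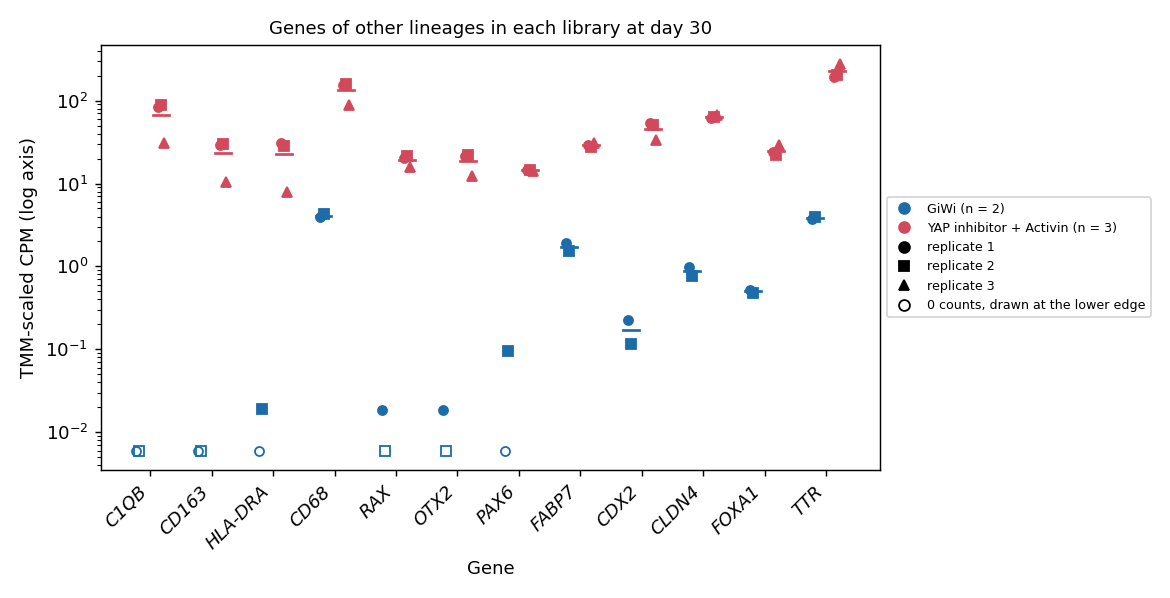
TMM-scaled CPM on a log axis for 12 genes of other lineages, with 1 point per library and bars for group means where no library is at 0; open symbols at the lower edge stand for 0 counts. For all 12 genes each library of the YAP inhibitor with Activin (n = 3) lay above both GiWi libraries (n = 2), as for CDX2 at 46.1 and 0.17 CPM.

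Markers of undifferentiated cells and of early mesoderm were low or mixed. POU5F1, a core pluripotency gene, had 0.5 and 0.5 counts in the GiWi libraries and 0.5, 0 and 1.5 in the others, too few to test. SOX2 rose from 3 counts in the GiWi libraries to 10.6 ± 5.65 CPM, a ratio of 364 with a 95% counting interval of 124 to 1767; it is also a gene of neural and squamous tissue. SALL4 rose from 0.57 ± 0.0678 to 3.42 ± 0.69 CPM (log2 fold change 2.58 ± 0.26), while SFRP2 fell from 909 ± 52.9 to 143 ± 31.2 CPM (log2 fold change -2.67 ± 0.18). TERF1 fell from 77.3 ± 3.27 to 33.5 ± 0.731 CPM (log2 fold change -1.21 ± 0.06). Of the 15 pluripotency genes, 3 rose, 7 fell and 5 did not pass (3 and 7 adjusted over the list alone). Camera on pluripotency genes gave an adjusted p = 0.277; their median log2 fold change was -0.64, with camera pointing down, and their mean 0.13. FGF8 rose from 0 counts to 1.15 ± 0.149 CPM, at least 40.2-fold higher. FOXA2 rose from 0.124 ± 0.0702 to 1.1 ± 0.244 CPM (log2 fold change 3.13 ± 0.44). PDGFRA, a receptor of mesenchymal cells, fell from 544 ± 24.9 to 161 ± 11.4 CPM (log2 fold change -1.76 ± 0.08). Of the 19 primitive streak and early mesoderm genes, 8 rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone). Camera on primitive streak and early mesoderm genes gave an adjusted p = 0.233. The pluripotency genes past the test numbered 6 without GiWi replicate 1, and the primitive streak genes 15 without replicate 3 of the YAP inhibitor with Activin. With scaling by library size alone, 7 primitive streak genes rose and 3 fell, and 5, 5 and 5 rose without GiWi replicate 1, GiWi replicate 2 or replicate 2 of the other group. Without GiWi replicate 2, 4 pluripotency genes fell, and without replicate 3 of the other group 5 rose. TNNT1 fell from 164 ± 14.1 to 20.1 ± 8.72 CPM (log2 fold change -3.03 ± 0.33). MYBPC2 fell from 2.1 ± 0.173 to 0.15 ± 0.0859 CPM (log2 fold change -3.81 ± 0.40). CHRND fell from 2.13 ± 0.268 to 0.298 ± 0.0469 CPM (log2 fold change -2.82 ± 0.23), while MYL1 rose from 0.114 ± 0.00282 to 1.09 ± 0.0331 CPM (log2 fold change 3.23 ± 0.26). Of the 21 skeletal muscle genes, 3 rose, 8 fell and 10 did not pass (3 and 8 adjusted over the list alone). Camera on skeletal muscle genes gave an adjusted p = 0.228, and 6 and 6 passed without GiWi replicate 1 or 2, while 5 rose without replicate 3 of the other group.

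Positional and signalling genes also differed. HOXC4 fell from 22.7 ± 2.17 to 3.48 ± 0.887 CPM (log2 fold change -2.71 ± 0.20, edgeR adjusted p = 2.87e-04). HOXB4 fell from 36.8 ± 1.15 to 13.7 ± 1.6 CPM (log2 fold change -1.42 ± 0.10). HOXB9 fell from 27.5 ± 1.35 to 9.86 ± 0.656 CPM (log2 fold change -1.48 ± 0.08), while HOXB6 rose from 10.4 ± 0.54 to 25.7 ± 0.984 CPM (log2 fold change 1.30 ± 0.07). Of the 28 HOX genes, 4 rose, 16 fell and 8 did not pass (5 and 16 adjusted over the list alone). Camera on HOX genes gave an adjusted p = 0.023, and an adjusted p = 0.746 with an estimated correlation; the call was lost with scaling by library size alone (adjusted p = 0.119), without GiWi replicate 1 or 2, 11 and 12 passed, and without replicate 3 of the other group 7 rose. In that replicate the HOX list lay at a median of 0.73 log2 from replicates 1 and 2. ALDH1A3, which makes retinoic acid, rose from 0.124 ± 0.0165 to 16.5 ± 1.06 CPM (log2 fold change 7.04 ± 0.16). CRABP1, which binds it, rose from 10.8 ± 1.61 to 56.8 ± 2.18 CPM (log2 fold change 2.40 ± 0.11), while MEIS2 fell from 213 ± 0.234 to 100.3 ± 6.05 CPM (log2 fold change -1.09 ± 0.07). Of the 23 retinoic acid genes, 5 rose, 14 fell and 4 did not pass (5 and 14 adjusted over the list alone). Camera on retinoic acid genes gave an adjusted p = 0.0315, and an adjusted p = 0.718 with an estimated correlation; the call was lost without replicate 1 of the YAP inhibitor with Activin (adjusted p = 0.0612) and with scaling by library size alone (0.0739), and 9 fell without GiWi replicate 2. LGR5, a Wnt target of intestinal stem cells, rose from 1.2 ± 0.0778 to 30.5 ± 1.56 CPM (log2 fold change 4.67 ± 0.10). RNF43 rose from 7.35 ± 0.0477 to 15.8 ± 0.35 CPM (log2 fold change 1.11 ± 0.07). CCND1, cyclin D1, rose from 125 ± 3.65 to 249 ± 12.1 CPM (log2 fold change 0.99 ± 0.06). Of the 28 WNT and beta-catenin target genes, 12 rose, 7 fell and 9 did not pass (12 and 7 adjusted over the list alone). Camera on WNT and beta-catenin target genes gave an adjusted p = 0.254 and pointed up. Without replicate 3 of the YAP inhibitor with Activin, 15 rose, 13 fell and camera pointed down (adjusted p = 0.626), and without GiWi replicate 2, 12 rose and 4 fell. TGFBI rose from 381 ± 14.5 to 1663 ± 46.8 CPM (log2 fold change 2.13 ± 0.06). Of the 31 activin, TGF-beta and BMP target genes, 10 rose, 12 fell and 9 did not pass (10 and 12 adjusted over the list alone). Camera on activin, TGF-beta and BMP target genes gave an adjusted p = 0.468; their median log2 fold change was -0.29, with camera pointing down, and their mean 0.06.

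Over the 33 lists, 16 passed camera with the preset correlation of 0.01, 7 higher and 9 lower, and 0 with an estimated correlation. By fry, 23 lists moved on balance in 1 direction and 33 changed in either direction. Fry does not compare a list with the other genes, and 57.1% of all tested genes were called. A pass there thus does not set a list apart. At an unadjusted p under 0.05 with the estimated correlation, 3 lists passed. That form rests on 3 residual degrees of freedom, so its 0 calls do not tell whether the lists shifted. Every other list that passed with the preset had an estimated correlation above 0.01, from 0.0243 for atrial to 0.945 for first heart field genes. The preset camera p-values of those lists may therefore be too small. The pacemaker list had an estimated correlation of -0.0397, below the preset 0.01. Its unadjusted camera p still went from 3.94e-07 to 0.0114.

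**Figure D3:**
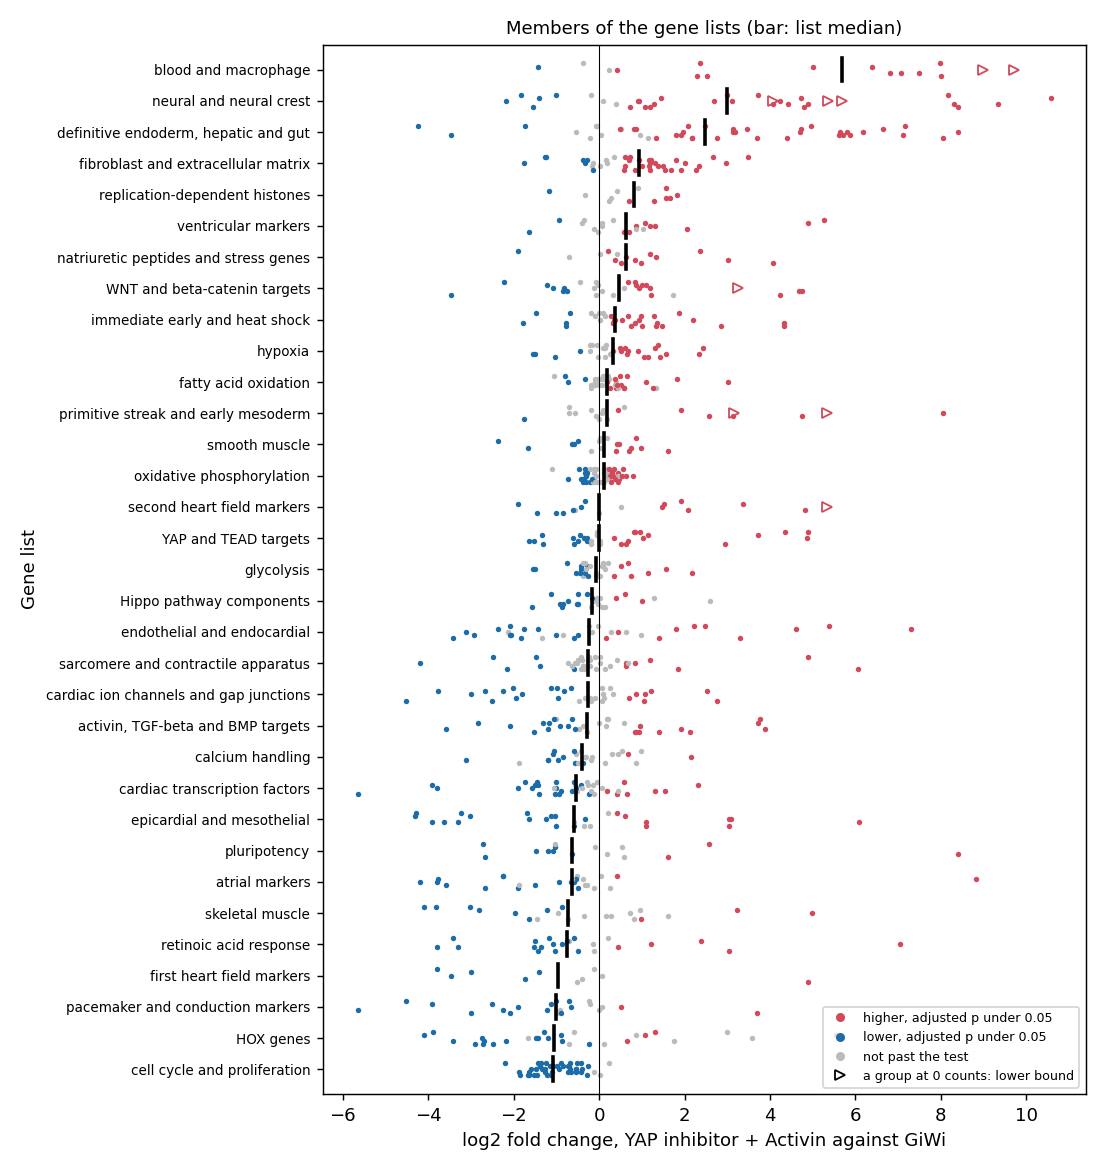
Log2 fold change (YAP inhibitor with Activin against GiWi) of each tested member of the 33 gene lists, with 1 point per gene, coloured by whether it passed edgeR's test, open triangles for lower bounds where a group had 0 counts, and black bars for list medians. The medians run from -1.07 for cell cycle genes to 5.69 for blood and macrophage genes; with scaling by library size alone the median of all tested genes moves from 0.01 to -0.18.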

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

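The unrounded counts and the sum of replicates 1 and 2 of the YAP inhibitor with Activin were the alternatives added after seeing the data, as was the estimated correlation under other settings than the main one. Over 17 settings, 141 of 148 named genes kept their direction and their side of the threshold in every setting that tested them (ACADL was not tested with the stricter filter), and no named gene changed direction; the exceptions were TNNT2, MYH7, MYL7, TNNI1, TNNI3, NKX2-5 and NR2F2. Leaving out 1 library at a time gave 5909 to 13115 changed genes, 3301 to 6721 higher and 2608 to 6394 lower, against 10065, 5325 and 4740. The lowest counts came without a GiWi library, which leaves 1 in that group, and the highest without replicate 3 of the YAP inhibitor with Activin, where 10014 of the 10065 calls were kept. The count of genes changed by at least 2-fold was 1683 on log2(FPKM + 1) against 4115, where the pseudocount shrinks the fold of low genes. Lists past camera numbered 0 with an estimated correlation, alone or with each of 9 other settings, against 16. Each of these fits leaves few residual degrees of freedom, so that difference does not tell whether the lists shifted. Of the 33 lists, 18 kept a count of passing members within 1.5 times in every setting. DESeq2 called 9919 genes, limma-voom with sample weights 12933, unrounded counts 10077, and the sum of replicates 1 and 2 as 1 library 8027. Whether the replicate numbers pair the samples could not be decided. Deviations of same-numbered libraries from their group mean correlated at 0.0508 and -0.0303 for numbers 1 and 2. The deviations of the 2 GiWi libraries are mirror images of each other, and replicate 3 shapes those of the other group, so these values cannot show a pairing or its absence. The replicate block gave 13576 changed genes. Depth limits genes near the floor of 3 counts, 0.0560 to 0.0742 CPM per library.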

Other observations

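The 8 gene lists of this part, the genes named from them and all of its tests were chosen after the largest changes had been seen, and several lists hold genes chosen from those changes, so their directions are descriptions and not independent evidence. Apart from the test of 1 outside source, the tests below replaced or restored earlier forms whose results had been seen, and a test of index exchange was dropped because the labels do not state pooling. Intestinal epithelium was represented by a broad set of transcripts in the libraries of the YAP inhibitor with Activin. In replicates 1, 2 and 3, CLCA1, a goblet cell product, measured 522, 489.7 and 77.7 CPM, MUC13, a mucin, 259, 266 and 80.6 CPM, SI, the brush border sucrase-isomaltase, 178, 171 and 29 CPM and CDH17, an intestinal cadherin, 192, 192 and 103 CPM. Of the intestinal genes, 29 rose, 0 fell and 1 did not pass among 30 tested (camera adjusted p = 1.13e-13, and an adjusted p = 0.356 with an estimated correlation). Hormone genes of the gut were present too, with CHGA, chromogranin A, at 269, 267 and 67.6 CPM and GCG, the glucagon precursor, at 145, 126 and 35 CPM, and of the enteroendocrine genes 17 rose, 0 fell and 2 did not pass among 19 tested (camera adjusted p = 6.43e-08, and an adjusted p = 0.356 with an estimated correlation). Retinal genes included the pigment cell gene TYRP1 at 53.6, 53.1 and 38.1 CPM, and 21 rose, 1 fell and 1 did not pass among 23 tested (camera adjusted p = 1.13e-13, and an adjusted p = 0.356 with an estimated correlation). Of the macrophage genes, 24 rose, 0 fell and 0 did not pass among 24 tested (camera adjusted p = 1.13e-13, and an adjusted p = 0.356 with an estimated correlation).

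Squamous and airway epithelial genes were higher in replicate 3 of the YAP inhibitor with Activin than in its replicates 1 and 2. KRT13 measured 28, 30.6 and 419 CPM, KRT5 8.44, 9.73 and 227 CPM and KRT4 16.6, 17.4 and 194 CPM in replicates 1, 2 and 3, and SCGB1A1, a secretory protein of the airway, 0.34, 0.329 and 46 CPM. Of the squamous genes, 12 rose, 1 fell and 7 did not pass among 20 tested (camera adjusted p = 0.0237, and an adjusted p = 0.658 with an estimated correlation), and of the lung and airway genes 2 rose, 0 fell and 3 did not pass among 5 tested (camera adjusted p = 0.314, and an adjusted p = 0.658 with an estimated correlation). Cartilage and bone genes were mixed: COL2A1, the main cartilage collagen, measured 367 and 374 CPM in GiWi and 38.8, 37.6 and 56.4 CPM in the others, and 8 rose, 3 fell and 6 did not pass among 17 tested (camera adjusted p = 0.0591, and an adjusted p = 0.356 with an estimated correlation). Kidney genes were few, and 6 rose, 2 fell and 1 did not pass among 9 tested (camera adjusted p = 0.314, and an adjusted p = 0.486 with an estimated correlation); LRP2, an endocytic receptor, measured 233 and 228 CPM in GiWi and 55.7, 56 and 104 CPM in the others. Of the 146 genes tested on these 8 lists, 32 are also on a list fixed earlier, and NEUROD1 is on 2 of the 8.

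Transcripts of intestine, retina, macrophages and squamous epithelium in the libraries of the YAP inhibitor with Activin could be RNA of 1 outside source. Such a source would keep its genes in 1 ratio, so the lists would differ between replicate 3 and replicates 1 and 2 by the same amount. The log2 difference of replicate 3 had a median of -1.14 (quartiles -1.79 and -0.89) for intestinal genes, -0.50 (quartiles -0.80 and -0.36) for retinal genes, -1.36 (quartiles -1.47 and -1.24) for macrophage genes and 3.36 (quartiles 2.53 and 3.85) for squamous genes. The squamous and intestinal medians were 4.50 apart, with quartiles that do not overlap. For these 2 lists, that argues against 1 source with its genes in 1 ratio. Both lists and the limits of the test were chosen after these values had been seen, so the size of the gap is a description. The gap does not tell whether 1 source gave the intestinal, retinal and macrophage transcripts. Several outside sources, and cells of other lineages formed under this protocol, stay open and were not tested.

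The lower cardiomyocyte transcripts of replicate 3 could reflect its depth or scaling, or a smaller share of cardiomyocytes as the single difference from replicates 1 and 2. Depth and scaling act on all genes of a library alike and cancel from the difference between the sarcomere genes and all tested genes, but that difference was -1.22 log2, with quartiles that do not overlap, which argues against both. All 39 sarcomere genes were lower, with an interquartile range of 0.43, as fewer cardiomyocytes would give, and a first test on these genes alone had gone with that explanation before the next one replaced it. A smaller cardiomyocyte share alone would raise the other cell types alike, but the squamous and macrophage medians were 4.72 log2 apart. These were picked as the highest and lowest of the intestinal, retinal, macrophage and squamous medians, on lists chosen after the results were seen. A fall in cardiomyocytes together with a change in which other cells were present stays open, as a hypothesis.

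The higher MYL2 and lower MYH6 with the YAP inhibitor and Activin could follow from a different share of cardiomyocytes, or from reads of MYH6 assigned to MYH7. A different share would move the other 37 sarcomere genes by about as much, but their median log2 fold change was -0.26 (quartiles -0.50 and 0.14), against -4.20 for MYH6 and 4.89 for MYL2, which argues against it as the whole cause. Reads that MYH6 lost to MYH7 would reappear there. The rise of MYH7 came to 40.5, 44.4 and 4.68% of the fall of MYH6 in CPM in replicates 1, 2 and 3. Relative to TNNT2 it came to 48.8, 54.3 and 57.4%. These values argue against misassigned reads as the whole of that fall. An earlier bound of 50% was met in CPM and would not be met relative to TNNT2. Reads lost at the same rate in every library would lower MYH6 in both groups alike. MYH6 held 82.2 ± 0.473% of the CPM of both genes in GiWi and 9.73 ± 0.522% in the other group. That argues against such a loss as the cause of the difference between the groups. Whether such a loss occurred in all libraries cannot be told from these values. A rate that differed between libraries was not tested. A difference in the type or maturity of the cardiomyocytes between the protocols, and the different treatment times, stay open as hypotheses that were not tested; purified cardiomyocytes of both protocols, treated for matched times, could decide between them.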
